A study of Homo sapiens with 3 samples.

How the data were processed

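Cells of 3 libraries, 1 per group, were analysed from deposited UMI count matrices for day 0 (BJ fibroblasts), day 3 and day 5, the last 2 labelled as induced neuron cells. The unit is UMI counts per gene and barcode, deposited without normalization, with 33538, 33538 and 36601 genes per the file headers. Per the submitters' processing notes reads were processed with Cell Ranger 4.0.0 on hg38 (GRCh38), and per the file headers the software names differ between libraries (3.0.1, cellranger-4.0.0 and Cell Ranger 4). The labels' protocols name nuclei suspensions and a chromatin accessibility kit for days 0 and 3, and about 10000 dissociated cells, a gene expression kit and the same accessibility kit for day 5, while each file holds gene counts. Whether introns and strand were counted is not given in the sources used here. The 3 deposited libraries held 17504, 11488 and 2037119 barcodes, so day 5 was unfiltered.

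In day 5, barcodes were called as cells when they held at least 1/10 of the UMIs of the 99th percentile of the top 10000 barcodes, a threshold of 2154 UMIs that called 9304. In all libraries cells needed at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5 and kept, since it marked under 0.5%. Of 33538 and 36601 genes, 32732 were in both feature tables by Ensembl ID. Genes of the Y chromosome and XIST were left out of the genes compared and of the genes that lead clusters, but not of the totals or of the clustering itself. Coordinates and intron lengths come from GENCODE 29 (GRCh38). UMIs were summed over kept cells per library and divided by the sum over shared genes for CPM, with exact Poisson 95% intervals. No test was run, since each group is 1 library and cells are not replicates. A gene was higher or lower when the ratio of CPM was at least 2, the larger CPM was at least 10 and the 2 intervals did not overlap. In the ratios used to call, rank and summarise genes, libraries under 3 UMIs were set at 3 UMIs, and a ratio printed against 0 is a lower bound from that level. The level is 0.0122, 0.160 and 0.0589 CPM at days 0, 3 and 5. A list member with 3 UMIs at day 0 and 0 at day 3 thus counts as higher at day 3, so list counts at low levels partly follow depth. A ratio printed against 1 to 3 UMIs used the UMIs themselves, with its exact interval. The limit given beside a count of 0 is 3 UMIs or 3 cells of the total, which is lower than the upper end of the exact interval. These rules, 33 gene lists, the markers and the named genes were set before the data were examined. Named genes were, per comparison, the 12 with the largest and 12 with the smallest log2 ratio among genes with the larger CPM at least 50 and separate intervals, leaving out unnamed clones, mitochondrial and ribosomal protein genes, plus up to 4 members per list at 10 CPM or more and 12 genes always named (TUBB3, MAP2, DCX, COL1A1, COL1A2, VIM, NR4A1, PDE4D, MKI67, TOP2A, CDKN1A and MALAT1). STMN2, COL6A3, MMP1, MMP3, CXCL8 and LIF join these in the plot of levels by day, chosen after their values were seen. List members needed at least 3 UMIs in 1 of the 2 libraries, and the percentile of a list's median came from 10000 random lists matched on expression in 20 bins. A few genes that these rules would name are not reported here. ICER, SNHG14 and TUG1 were in the lists and not found among the shared genes. In each comparison 16 lists were treated as main results, a choice made after the data were seen, and the others only described. On simulated counts of 32636 genes, run after the comparisons, the rule recovered 50 of 50 genes at 3-fold, 50 of 50 at 6-fold and 50 of 50 at 12-fold, and 0 of 50 at 1.5-fold, and called 0 unchanged genes in each comparison. The rule asks for a ratio of at least 2, so genes at 1.5-fold could hardly pass. With 1 library per group, variation between libraries could not be estimated, so these counts give no rate of false calls between real libraries. Random lists with no effect lay within the central 95% in 39, 38 and 37 of 40 cases.

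Each library was clustered alone in scanpy 1.11.5 with igraph 0.11.9 (log counts per 10000, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5). Shares of cells used cells thinned to 1000 UMIs over all genes, with exact binomial 95% intervals. The thinned alternative of the comparisons counted UMIs over shared genes and left out 2391 cells at day 0 and 3013 at day 3. A cluster was neuron-like with at least 3 pan-neuronal markers 2-fold above the rest, a rule of size set after the clusters were seen, with 4 and 10 as alternatives, at resolution 1 too. Alternatives tried were other cell calls (3000 expected cells, every barcode of 1000 UMIs), a strict filter (2000 UMIs, 1000 genes, 10% mitochondrial), no filter, TMM (edgeR 4.0.16 in R 4.3.3), the median of ratios, totals without mitochondrial and ribosomal genes, mean per-cell CPM, thinning, other CPM limits, and subtraction of the profile of barcodes with 10 to 100 UMIs. Added after seeing the data were leaving out cells above the 95th percentile of UMIs, genes with under 20000 bases of intron, day 0 barcodes under 3000 UMIs, list members at 10 CPM, and subtraction of the 500 to 1000 UMI profile. The limit on free RNA was added too: it takes each gene of the barcode profile at the highest ratio of a ribosomal protein gene between cells and barcodes, from summed UMIs for CPM (21.5% and 41.95% for the 2 profiles) and from the mean of per-cell fractions for shares, within each cluster for its own values. One exploratory pass came before the comparison code. Numbers came from Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.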

Results

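Single-cell RNA sequencing covered 3 libraries of a human fibroblast induction series, 1 library per group. The day 0 library held BJ cells, an established human fibroblast line, and the day 3 and day 5 libraries held cells labelled as induced neuron cells. Per the labels, the culture media held forskolin, an activator of adenylyl cyclase that raises cAMP, and it was withdrawn on day 5, while whether the day 0 cells had met it is not given in the sources used here. After filtering, 16773 cells with 246546451 UMIs remained at day 0, 11454 cells with 18743865 UMIs at day 3 and 9219 cells with 51708522 UMIs at day 5. The median cell held 14039, 1324 and 4374 UMIs, and 3837, 827 and 2384 genes, in that order. Levels are CPM, a gene's UMIs relative to all UMIs on the 32732 genes in both feature tables, with exact Poisson 95% intervals in parentheses. With 1 library per group there was no replicate check and no test, so all intervals, including the binomial ones on shares, cover counting error only and each comparison is between libraries. The labels' protocols name nuclei suspensions for days 0 and 3 and dissociated cells for day 5. The stated preparation thus differs along with the day. Days 0 and 3 share a stated preparation but differ in make-up. Mitochondrial UMIs took 6.45% and 0.745%, ribosomal protein UMIs 17.1% and 4.35%, and MALAT1 3.14% and 21.6%. A difference in preparation between days 0 and 3 is not excluded, and their comparison is not free of it.

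The comparison of day 3 with day 0 asks what distinguished the early induction library from the starting fibroblasts. Inflammatory and secretory genes were higher at day 3, with 20 of 23 measured members at least 2-fold higher and 0 lower. Contractile and actin cytoskeleton genes were lower, with 14 of 18 members at least 2-fold lower and 0 higher. The chemokine CXCL5 stood at 399 CPM (390 to 408) at day 3 and 1.49 (1.34 to 1.65) at day 0, a 269-fold difference. Against 10000 random lists matched on expression, the inflammatory median lay at percentile 100 and the contractile median at 0.03. The contractile median log2 ratio of -1.97 was near that of ribosomal proteins (-2.11), heat shock (-1.73) and nuclear oxidative phosphorylation genes (-1.65). A drop of this size was therefore not particular to contractile genes. The smooth muscle actin-binding gene TAGLN stood at 4.81 CPM (3.87 to 5.91) against 1374 (1370 to 1379), 286-fold lower.

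Other inflammatory members were VCAM1, an adhesion molecule, at 19.1 against 0.0243 CPM, the chemokine CCL7 at 27.4 against 0.0933, and the cytokine IL1A at 18.2 against 0.0649. In the contractile list, the myosin light chain MYL9 stood at 20.6 against 804 CPM and CNN1 at 0.428 against 13.6. YAP and TEAD targets had 9 of 15 members lower and 2 higher, among them NT5E at 19.6 against 568 CPM. Beside these groups, mitochondrial transcripts took 0.745% of UMIs at day 3 and 6.45% at day 0, and ribosomal protein transcripts 4.35% and 17.1%.

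Neural gene groups were mixed at day 3. Of the neuronal transcription factors, 12 of 16 measured members were higher and 0 lower, and of the 6 that reached 10 CPM, a limit chosen after the data were seen, 5 were higher. Against matched random lists their median lay at percentile 96.4, within the central 95%. Of the measured pluripotency and muscle genes, 5 of 6 and 6 of 7 counted as higher and 0 as lower, but 0 of either reached 10 CPM. Those medians lay at percentiles 94.1 and 33.4, and epithelial genes had 4 higher and 3 lower of 11. Genes with few UMIs at day 0 and 0 at day 3 count as higher, because 3 UMIs are 0.160 CPM at day 3 and 0.0122 at day 0. SOX4 stood at 1801 against 155 CPM and EBF3 at 33.7 against 0.633. Pan-neuronal genes had 11 members higher and 10 lower of 27, but among the 8 at 10 CPM or more 1 was higher and 4 were lower, and the list's median lay at percentile 0.44, below the central 95%. The synaptic vesicle gene SYP was higher, at 17.9 against 0.560 CPM, and the ubiquitin hydrolase UCHL1 lower, at 156 against 403. The neuronal tubulin TUBB3 stood at 0.855 CPM (0.489 to 1.39) against 1.79 (1.63 to 1.96), and the dendritic protein gene MAP2 at 2.24 (1.62 to 3.03) against 1.87 (1.70 to 2.05), intervals that overlap. DCX, a gene of migrating young neurons, had 0 UMIs in both libraries, which allows up to 0.160 CPM at day 3 and 0.0122 at day 0. Neural progenitor genes had 7 members higher and 4 lower of 14, with the median at percentile 33.3. Neurotransmitter and subtype genes had 9 higher and 1 lower of 13, with the median at percentile 9.88, but 3 higher with cells thinned to 1000 UMIs, and 0 of them reached 10 CPM in either library. Genes with over 100000 bases of intron took 13.7% of UMIs at day 3 and 8.84% at day 0.

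Fibroblast genes went both ways, with 10 of 28 higher and 7 lower at day 3. The growth factor receptor PDGFRA stood at 1281 against 52.7 CPM, TWIST1 at 227 against 20.7, S100A4 at 912 against 106 and THY1 at 23.1 against 223. COL1A1 was lower, at 380 against 2027 CPM, COL1A2 higher, at 2397 against 917, and the filament gene VIM lower, at 1405 against 5146. Targets of cAMP and CREB had 13 members higher and 10 lower of 29. PTGS2, which makes prostaglandin precursors, stood at 546 against 13.6 CPM, the phosphodiesterase PDE4D at 132 against 6.95, NR4A1 at 64.2 against 313 and FOSB at 0.428 against 262. S phase genes had 6 higher and 17 lower of 41, and UHRF1 stood at 6.41 against 41.8 CPM. G2 and M phase genes had 4 higher and 7 lower of 53, with MKI67 at 38.3 against 56.8 CPM and TOP2A at 358 against 121. In the p53 list 9 of 20 were higher and 2 lower, with GDF15 at 425 against 38.1 CPM and CDKN1A, a cell cycle inhibitor, at 173 against 573. Cholesterol synthesis had 3 higher and 9 lower of 22, including INSIG1 at 2.94 against 268 CPM. With TMM, the fibroblast genes higher were 5, the cAMP and CREB targets 7 and the p53 genes 4, and the S phase genes lower were 27, the G2 and M phase genes 29 and the cholesterol genes 17.

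Mitochondrial, ribosomal protein and oxidative phosphorylation transcripts were lower at day 3. Mitochondrially encoded genes had 12 of 13 members lower, cytosolic ribosomal proteins 27 of 29 and nuclear oxidative phosphorylation genes 21 of 32, each with 0 higher. Nuclear retained RNAs had 4 of 5 members higher and 0 lower, but 2 higher with TMM or the median of ratios, and MALAT1 stood at 216450 CPM against 31449. Across genes, 3922 were higher and 1995 lower of 10423 with at least 10 CPM, so 66.3% of those that differed were higher. The median log2 ratio over 14614 genes with at least 10 UMIs in every library was 0.81. Scaling by TMM gave 23.8% higher, the median of ratios 35.7%, and totals without mitochondrial and ribosomal protein genes 55.6%. Relative to the median gene, the list medians were 2.94 for inflammatory genes, -2.78 for contractile genes and -4.50 for mitochondrial genes, a measure that no scaling of a library can change. Not taken relative to it, the 3 medians were 3.75, -1.97 and -3.69, and with TMM 2.55, -3.17 and -4.89. The medians of the fibroblast list (0.27), the pan-neuronal list (0.36), the G2 and M phase list (0.15) and the p53 list (0.75) turn negative under TMM, at -0.93, -0.84, -1.05 and -0.45, and under the median of ratios.

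Single genes furthest above day 0 were led by MT1M, BMP5, RORB, CP, NFIB, IGFBP2, MARCH1 and CACNB2. Of the day 3 UMIs of RORB, NFIB and CP, 90.6%, 77.3% and 60.1% lay in day 3 cluster 2, which held 21.8% of cells at a median of 986 UMIs. RORB stood at 342 CPM (321 to 363) in that cluster and 7.04 in the other cells, NFIB at 246 and 14.4, and MT1M at 199 and 53.2, while BMP5 stood at 62.3 and 126 and IGFBP2 at 610.0 and 593. IGFBP2, a binding protein of insulin-like growth factors (ENSG00000115457, GRCh38 chromosome 2, 216632828 to 216664436), stood at 597 CPM (586 to 608) against 0.844 (0.733 to 0.967), a ratio of 707. MT1M belongs to a family of near-identical metallothionein genes and MTRNR2L6 copies mitochondrial sequence, so their levels are uncertain, as are those of the antisense genes HMGA2-AS1 and STARD4-AS1 because the use of strand is not given in the sources used here. Genes furthest below included LCE2A and KRTAP2-3, both members of gene families, FOSB, CLDN1, TAGLN, C12orf75, LYPD1, INSIG1, HBEGF, HMGA1 and APCDD1L. LCE2A had 0 UMIs at day 3 and 197 CPM at day 0, at least 1230-fold lower.

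**Figure D1:**
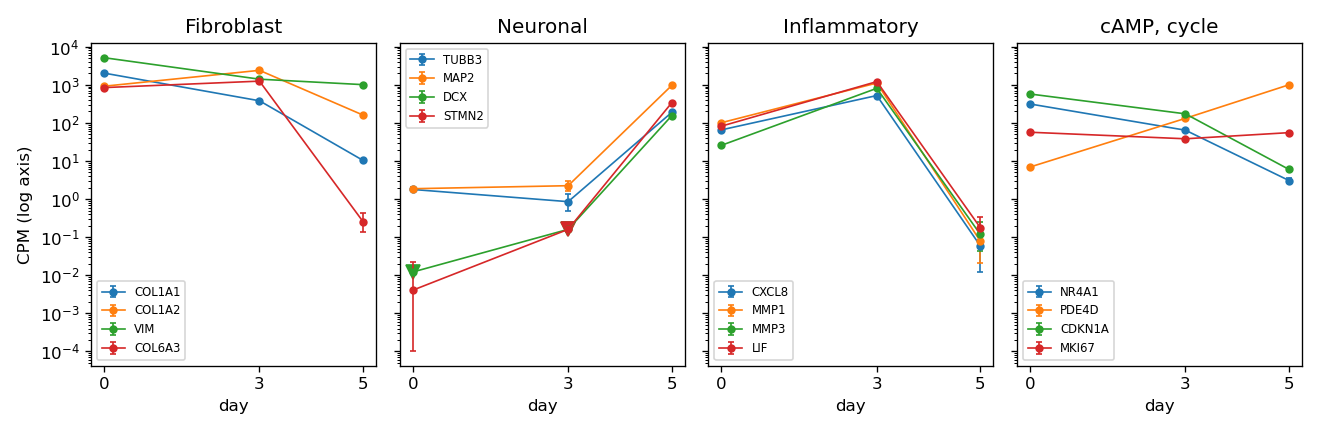
Level of 16 genes in the 3 libraries, in CPM on a log axis, against day, with 1 library per point, exact Poisson 95% intervals as bars and large triangles at the level of 3 UMIs where a library had 0 UMIs. The 4 neuronal genes are highest at day 5, where MAP2 stood at 960 CPM, and the 4 inflammatory genes at day 3, where MMP1 stood at 1113.

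The comparison of day 5 with day 3 asks what separated the later induction library from the earlier one. Neuronal genes were higher at day 5, with 28 of 32 measured pan-neuronal members higher and 2 lower. Inflammatory and secretory genes were lower, with 22 of 23 members lower and 0 higher, and so were fibroblast genes, with 23 of 28 lower and 0 higher. The cytoskeletal regulator STMN2 stood at 337 CPM (332 to 342) at day 5 with 0 UMIs at day 3, and the collagenase gene MMP1 stood at 0.0786 CPM (0.0214 to 0.201) against 1113 (1098 to 1128).

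Among neuronal genes, DCX stood at 154 CPM (151 to 158) against 0 UMIs, MAP2 at 960 (951 to 968) against 2.24, TUBB3 at 188 (185 to 192) against 0.855 and ELAVL4 at 95.7 against 0 UMIs. The barcodes of 500 to 1000 UMIs in the same library carried TUBB3 at 809 CPM and DCX at 163, so these levels are no higher in cells than in those barcodes, while MAP2 stood at 515 in them. At the limit on its share of a cell, free RNA would bring up to 249 CPM of TUBB3, 44.9 of DCX and 189 of MAP2. Neuronal transcription factors had 22 of 27 members higher and 3 lower, and 13 of the 15 at 10 CPM or more were higher, including MYT1L at 164 against 0.802 CPM and POU3F2 at 56.2 against 0 UMIs. Neural progenitor genes had 15 higher and 4 lower of 19, and SOX2, a neural stem cell factor, stood at 76.6 CPM with 0 UMIs at days 0 and 3. Neurotransmitter and subtype genes had 21 higher and 1 lower of 22, and of the 8 at 10 CPM or more all 8 were higher, including the glutamate receptor GRIN2A at 403 against 0.0534 CPM and SST, the somatostatin gene, at 28.2 against 0 UMIs. Genes with over 100000 bases of intron took 46.6% of UMIs at day 5 and 13.7% at day 3.

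The fibroblast list held COL6A3 at 0.255 CPM against 1247, PDGFRA at 0.727 against 1281, COL1A1 at 10.3 against 380, COL1A2 at 160 against 2397 and VIM at 1009 against 1405. The VIM log2 ratio went from -0.48 to 0.085 with every day 5 barcode of 1000 UMIs called. Inflammatory members included CXCL8 at 0.0589 against 522 CPM, MMP3 at 0.118 against 808 and the cytokine LIF at 0.177 against 1211. Targets of cAMP and CREB had 6 members higher and 18 lower of 29. AREG, an epidermal growth factor family ligand, had 0 UMIs at day 5 and 1434 CPM at day 3, at least 24344-fold lower. PDE4D was higher, at 1002 against 132 CPM, a ratio not set apart from the trend with intron length given below. The p53 list had 16 of 20 lower and 0 higher, with CDKN1A at 5.99 against 173 CPM. Cholesterol synthesis genes had 17 of 22 higher and 1 lower, with CYP51A1 at 155 against 1.23 CPM. S phase genes had 19 higher and 2 lower of 41, and G2 and M phase genes had 16 higher and 5 lower of 53. MKI67 stood at 55.5 against 38.3 CPM and TOP2A at 179 against 358. The MKI67 log2 ratio went from 0.54 to -0.31 with the profile of the 500 to 1000 UMI barcodes subtracted. Mitochondrially encoded genes had 13 of 13 higher, ribosomal proteins 15 of 29 lower and 0 higher, and oxidative phosphorylation genes 12 of 32 lower and 0 higher. The 2 lower counts depend on the processing, at 3 and 4 with every day 5 barcode of 1000 UMIs, 3 and 7 with the strict filter, 5 and 9 with cells thinned to 1000 UMIs, 9 and 10 with the median of ratios, and 29 and 30 with the profile of the 500 to 1000 UMI barcodes subtracted. Contractile genes had 2 higher and 8 lower of 18, and nuclear retained RNAs had 5 of 5 lower, including MALAT1 at 73541 against 216450 CPM.

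Across genes, 4597 were higher and 3626 lower of 12610, so 55.9% of those that differed were higher, and the median log2 ratio of all genes was -0.22. Relative to it, list medians were 5.87 for pan-neuronal, -8.45 for inflammatory and -4.53 for fibroblast genes. Not taken relative to it, these were 5.65, -8.67 and -4.75, and with TMM 5.71, -8.60 and -4.69. Against matched random lists the pan-neuronal median lay at percentile 100 and the other 2 at 0. Genes with under 20000 bases of intron, a limit chosen after the data were seen, gave 620 higher and 2541 lower. Over 12542 genes at 10 CPM or more outside the neuronal lists, total intron length and the log2 ratio had a Spearman rho of 0.58 across genes, which are not independent replicates. For day 5 over day 0 this rho was 0.52. Random lists were matched on expression and not on intron length, so list counts and percentiles of day 5 are not free of this trend. Nor are day 5 ratios and shares of single genes, PDE4D among them. For day 5 over day 3, genes outside the neuronal lists with over 200000 bases of intron had a median log2 ratio of 3.57.

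The 12 genes furthest above day 3 were ERBB4, NRXN3, CTNND2, TENM2, NTRK2, DCC, RBFOX1, ADGRB3, FRAS1, ADARB2, TMEM178B and ZNF536, and the shortest total intron among them was 338160 bases, in NTRK2. NTRK2, the receptor of brain-derived neurotrophic factor (ENSG00000148053, GRCh38 chromosome 9, 84668551 to 85027070), had 0 UMIs at day 3 and 1020 CPM (1012 to 1029) at day 5, at least 6365-fold higher, and 1402 CPM in the barcodes of 500 to 1000 UMIs. ERBB4, a neuregulin receptor (ENSG00000178568, chromosome 2, 211375717 to 212538841), had 2 UMIs at day 3 and 1551 CPM at day 5, a ratio of 14510 (4017 to 119810). The 12 furthest below were AREG, MMP1, FENDRR, PTGS2, CXCL8, HGF, MMP3, LIF, TBX3, TCF21, COL6A3 and TBX2. HGF, hepatocyte growth factor, stood at 0.118 against 1026 CPM and TBX3, a limb and skin transcription factor, at 0.0589 against 345.

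The comparison of day 5 with day 0 asks how far the later library stood from the starting fibroblasts. Fibroblast and contractile genes were lower, with 25 of 28 and 18 of 18 members lower and 1 and 0 higher. Pan-neuronal genes were higher, with 27 of 32 members higher and 1 lower. COL1A1 stood at 10.3 CPM (9.48 to 11.3) against 2027 (2022 to 2033), 196-fold lower, and NCAM1, a neural adhesion molecule, at 806 CPM (798 to 814) against 0 UMIs, at least 66238-fold higher.

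LGALS1 stood at 1.94 against 5644 CPM, MYL9 at 12.2 against 804 and TAGLN at 30.4 against 1374. GPM6A, a neuronal membrane glycoprotein, had 436 CPM with 1 UMI at day 0. Neuronal transcription factors had 24 of 27 higher and 1 lower, progenitor genes 15 of 18 higher and 2 lower, and neurotransmitter genes 22 of 22 higher. NR4A1 stood at 3.06 against 313 CPM, PDE4D at 1002 against 6.95 and CDKN1A at 5.99 against 573. Targets of cAMP and CREB had 7 higher and 19 lower of 29, inflammatory genes 2 higher and 17 lower of 23, and the p53 list 2 higher and 13 lower of 20. Cholesterol synthesis had 12 higher and 1 lower of 22, with HMGCS1 at 283 against 15.5 CPM. Ribosomal proteins were lower in 29 of 29 members and oxidative phosphorylation genes in 29 of 32, while mitochondrially encoded genes had 2 of 13 lower and 0 higher, but 10 lower with TMM, and 6 with the median of ratios or with the 500 to 1000 UMI profile subtracted. Nuclear retained RNAs had 2 higher and 3 lower of 5, S phase genes 14 higher and 5 lower of 41, and G2 and M phase genes 17 higher and 7 lower of 53. With TMM the cholesterol genes higher were 5, the S phase genes 5 and the G2 and M phase genes 3. Ribosomal protein transcripts took 2.20% of UMIs at day 5 and 17.1% at day 0.

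Across genes, 5919 were higher and 3140 lower of 12071, so 65.3% of those that differed were higher, against 43.1% with TMM and 52.4% with the median of ratios, and the median log2 ratio was 0.71. Relative to it, list medians were 7.10 for pan-neuronal, -5.04 for fibroblast and -4.11 for contractile genes, at percentiles 100, 0 and 0 of matched random lists. Not taken relative to it, these were 7.81, -4.33 and -3.40, and with TMM 6.67, -5.46 and -4.54. The S phase median (0.40) and the G2 and M phase median (0.47) turn negative under TMM, at -0.74 and -0.66. Genes with under 20000 bases of intron gave 883 higher and 2155 lower.

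The 12 genes furthest above day 0 were PTPRD, DCC, RBFOX1, NCAM1, NTRK2, TSHZ2, ADARB2, RFX4, ZNF536, NKAIN3, ERBB4 and CTNNA2. DCC, a netrin receptor of growing axons (ENSG00000187323, GRCh38 chromosome 18, 52340172 to 53535903), had 0 UMIs at day 0 and 1420 CPM (1409 to 1430) at day 5, at least 116630-fold higher. The 12 furthest below were TM4SF1, MTRNR2L8, AREG, FGF5, PLAU, TBX3, LCE2A, MT2A, COL6A3, FOXF1, TBX2 and PITX1. TM4SF1, a membrane protein gene (ENSG00000169908, chromosome 3, 149369022 to 149377865), had 727 CPM at day 0 and 0 UMIs at day 5, at least 12343-fold lower. MT2A stood at 3.46 against 11467 CPM, and it, LCE2A and MTRNR2L8 share sequence with relatives, so their levels are uncertain.

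**Figure D2:**
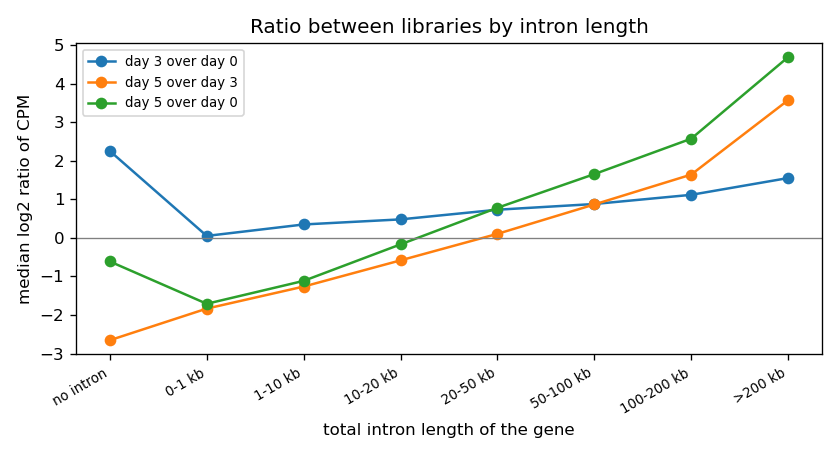
Median log2 ratio of CPM between libraries (vertical axis) for genes grouped by total intron length (horizontal axis), over 12542 genes with at least 10 CPM outside the neuronal lists. Lines join group medians for each pair of libraries, and the day 5 over day 3 median goes from -2.65 in 372 genes with no intron to 3.57 in 1309 genes with over 200000 bases.

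Clustering each library alone asked which cell states it held. The day 5 cells formed 11 clusters, and 5 of them had at least 3 pan-neuronal markers 2-fold above the other cells and were neuron-like, holding 2957 of 9219 cells, 32.1% (31.1 to 33.0). This rule was set after the clusters were seen, and the share was 17.6% with at least 10 markers and 17.1% at resolution 1 with at least 4. Cluster 5 was led by VWDE, ROBO3 and the glutamate transporter SLC17A6, cluster 6 by ADARB2, the glycine transporter SLC6A5 and GAD2, and cluster 7 by VXN, NEUROD4 and EBF2. Cluster 2 was led by CNTN5 and GABRA2 and cluster 10 by RELN and NXPH1. Cluster 1, with 472 cells or 5.12%, had 11 fibroblast list genes above the other cells, COL1A1 and COL3A1 among them, and only UCHL1 of the pan-neuronal list. Against the barcodes of 500 to 1000 UMIs in the same library, 7 of these 11 genes stood higher in cluster 1 and 3 lower beyond their intervals, with COL1A1 at 79.3 against 30.5 CPM, COL3A1 at 19.6 against 20.3 and COL1A2 at 399 against 513. With both thinned to 500 UMIs, COL1A1 was seen in 1.48% of cluster 1 cells (0.598 to 3.03) and 1.5% of those barcodes and COL1A2 in 18.9% (15.4 to 22.7) and 22.0%. All 11 genes stood above the level that free RNA at its limit would bring to the cluster. The 11 were chosen for being high in these same cells, so this count and the 7 of 11 lend no separate support. Free RNA would show COL1A2 in up to 7.12% of cluster 1 cells and COL1A1 in up to 0.632%, which lies within the interval of the COL1A1 share, so by share only COL1A2 is above it. Cluster 9, with 1475 cells, had 33 G2 and M phase genes above the other cells and was cycling-like by its markers. Of these, 24 stood higher in the cluster than in the barcodes and 2 lower, with CDC25C at 144 against 15.3 CPM and CENPF at 335 against 766. After thinning, at least 2 UMIs of the list were seen in 66.0% of its cells against 78.7% of the barcodes, TOP2A in 14.0% against 25.6% and MKI67 in 4.41% against 9.63%, where free RNA at its limit would give up to 19.5%, 8.03% and 2.85%. Of the 33 genes, 32 stood above the level of free RNA, but they too were chosen for being high in these cells, so the counts of them lend no separate support.

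The day 0 cells formed 6 clusters and the day 3 cells 4. By the same rule of 3 markers, day 3 cluster 2, 21.8% of cells, would be neuron-like, with NCAM1, GAP43 and ANK3 above the other cells, and it would not be with at least 4, while 0 day 0 clusters met the rule. Cluster 3 was cycling-like in each, led by MKI67, CENPF and TOP2A in 3180 cells at day 0 and by GTSE1 and CDC25C in 761 cells at day 3. At day 3 the G2 and M phase list was raised in cluster 2 as well. It stood there at 4291 CPM, against 7167 in cluster 3, 1313 in cluster 0 and 1096 in cluster 1. Day 0 clusters 0 and 2, with 3636 and 3718 cells, held a median of 2207 and 896 UMIs against 14039 in the library and were left unnamed. MALAT1 stood at 1141 and 3665 CPM in them and at 27600 to 56310 in the other day 0 clusters. Whether these barcodes are intact cells is not known. They enter the number of kept cells and, from 1000 UMIs, the day 0 shares. COL1A1 was seen in 72.3% of day 0 cells with the strict filter against 57.6% as reported. Day 3 cluster 1, with 744 cells, was led by mitochondrial genes, and cluster 2, with 2496 cells, by RORB, GNAO1, FUCA1 and HES1. Doublets were not removed because the caller marked 0, 1 and 1 cells.

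The share of cells with marker UMIs asked how widely each gene was seen when every cell was thinned to 1000 UMIs. MAP2 was seen in 51.5% of day 5 cells (50.5 to 52.5), 0.225% at day 3 and 0.146% at day 0, and DCX in 12.5% (11.9 to 13.2) at day 5 and 0 cells at days 0 and 3, which allows up to 0.0209% and 0.0355%. PDE4D was seen in 49.9%, 11.98% and 0.514% of cells at days 5, 3 and 0, COL1A1 in 0.868%, 31.5% and 57.6%, and COL1A2 in 15.2%, 89.0% and 39.2%. VIM was seen in 67.0%, 72.8% and 96.6%, TUBB3 in 19.4%, 0.106% and 0.160%, NR4A1 in 0.315%, 6.08% and 18.7%, and CDKN1A in 0.607%, 15.2% and 30.8%. For VIM day 5 was above day 3 with thinning to 2000 UMIs, at 86.3% against 84.6%, and without thinning, at 99.1% against 86.1%. With the strict filter it was too, at 65.7% against 64.0%, so no order of VIM between these days is read. At least 2 UMIs of the G2 and M phase list were seen in 63.8% of cells at day 5, 48.4% at day 3 and 37.6% at day 0. For this list day 3 was below day 0 without thinning, at 67.5% against 71.3%, and with the strict filter, at 40.4% against 44.5%, so no order between these 2 days is read. MKI67 was seen in 5.28%, 3.44% and 4.06%, and TOP2A in 15.9%, 21.1% and 7.48%. The leukocyte gene PTPRC, a background gene chosen after the data were seen, was seen in 0.325%, 0.154% and 0% and HBB in 0%, 0.0118% and 0.00695%, where the 0 cells allow up to 0.0209% for PTPRC at day 0 and 0.0325% for HBB at day 5. Thinning left out 2388 cells at day 0, 2999 at day 3 and 0 at day 5. Without thinning MAP2 was seen in 88.0% of day 5 cells, 0.367% at day 3 and 2.51% at day 0, DCX in 37.1% at day 5, COL1A1 in 3.33%, 42.5% and 67.8%, and TUBB3 in 60.3%, 0.140% and 2.58%.

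Day 5 held the barcodes of lower depth, so its shares were set against the 500 to 1000 UMI barcodes, with cells and barcodes thinned to 500 UMIs from medians of 4374 and 753. TUBB3 was seen in 10.2% of cells and 32.6% of those barcodes, VIM in 44.1% and 93.5%, COL1A2 in 8.12% and 22.0%, TOP2A in 9.02% and 25.6%, MKI67 in 3.28% and 9.63%, COL1A1 in 0.412% and 1.5%, CDKN1A in 0.325% and 1.24%, and the G2 and M phase list in 36.3% and 78.7%. NR4A1 was seen in 0.163% and 0.144%, DCX in 7.12% and 7.47%, MAP2 in 32.7% (31.7 to 33.6) and 22.7% (21.9 to 23.6), and PDE4D in 32.6% and 11.2%. Free RNA can make up only part of a cell, at most 26.0% of UMIs with the profile of those barcodes and 49.7% with that of the barcodes of 10 to 100 UMIs, taken from the highest ratio of a ribosomal protein gene between cells and barcodes. At that limit, added after the data were seen, free RNA of either profile would show MAP2 in up to 10.5% of cells, PDE4D in 8.18%, DCX in 2.61%, COL1A2 in 6.86%, TOP2A in 7.59%, MKI67 in 2.69% and the G2 and M phase list in 17.9%, each below the share seen in cells. It would show TUBB3 in up to 13.6%, VIM in 56.0%, COL1A1 in 0.608% and CDKN1A in 0.354%. For these 4 genes the shares seen are not above this limit. VIM lay below it with either profile, at 44.1% (43.1 to 45.1) against 52.0% and 56.0%. The limit is thus higher than what free RNA brought, and a share not above it does not show free RNA as its source.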

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

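The tests of nuclei, of introns, of free RNA, of cytosolic loss and of the feature table were chosen after the results were seen, and the tests of depth and of another origin were written before.

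Data outside the comparisons stood out in 2 results. Barcodes with 500 to 1000 UMIs, which are not among the kept cells, held 35.7% of day 5 UMIs. Genes found only in the day 5 table held 1.52% of the UMIs of kept day 5 cells, led by RMST at 1543, SNHG14 at 668 and SOX2-OT at 453 CPM of all genes.

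Mitochondrial and ribosomal protein transcripts were lower and MALAT1 was higher at day 3 than at day 0. Lower depth per cell is not decided by thinning every cell to 1000 UMIs, which gave a mitochondrial list median log2 ratio of -3.90. Random thinning leaves the expected fractions of each cell unchanged, so it could hardly move this median. Nuclei in place of whole cells at day 3 and a response to 3 days of induction cannot be told apart. Of the 4 members of the nuclear retained list other than MALAT1 (NEAT1, MEG3, KCNQ1OT1 and NORAD), 3 were higher and 0 lower. Their median lay at percentile 95.5 of matched random lists, within the central 95%. With 4 genes, not all of which need be confined to the nucleus, this test cannot decide. The protocol text names nuclei for both libraries, yet day 0 held 6.45% mitochondrial UMIs against 0.745% at day 3. These explanations stay open, and the response to induction was not tested.

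Pan-neuronal genes were higher at day 5 than at day 3. Counting of intron reads at day 5 alone may add to this, since intron length and log2 ratio had a rho of 0.58 over genes outside the neuronal lists, but 8 of 11 pan-neuronal members with under 20000 bases of intron were at least 2-fold higher, which argues against it as the whole cause. Those 11 members were not split by the free RNA limit given next, and intron reads and free RNA acting together were not tested. Free RNA as the source of every member is argued against, because 23 of 32 members, MAP2 and DCX among them, stood higher in cells than free RNA could bring with its share of a cell at most the highest ratio of a ribosomal protein gene between cells and barcodes, 21.5% for the profile of 500 to 1000 UMI barcodes and 41.95% for that of 10 to 100. Of 32 oxidative phosphorylation genes, 29 did not pass this level. Passing is not particular to neuronal genes. By the ratio to the 500 to 1000 UMI barcodes alone, 1 of 32 pan-neuronal, 2 of 25 fibroblast and 3 of 53 G2 and M phase genes were at or below the highest ribosomal ratio. For oxidative phosphorylation and heat shock these were 22 of 32 and 5 of 11. For the other 9 pan-neuronal members, TUBB3 among them, free RNA and RNA of the cells cannot be told apart at this limit, which is an upper bound. Induction by day 5 stays open and untested, as the day goes with the preparation and the software.

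Fibroblast genes were lower at day 5 than at day 3 in 23 of 28 members and than at day 0 in 25. The list still took 944 to 3315 CPM in each day 5 cluster. That sum includes VIM, which stood far above COL6A3, PDGFRA and COL1A1 at day 5, so it does not show that these members persisted. Loss of cytosolic RNA is argued against, since the 500 to 1000 UMI barcodes carried the fibroblast list at a median log2 ratio to day 0 of -3.65 and the ribosomal list at -0.69. Missing genes are not the source, since compared genes share an ID by design and 28 of 28 fibroblast genes kept theirs. Changed gene models under the same ID were not tested. Cells with UMIs of at least 3 of the 12 genes furthest above day 5 at day 3 numbered 0 of 9219 at day 5, which allows up to 0.0325%, and made up 98.8% at day 3. Cells of another origin and a conversion of every cell cannot be told apart by this, because both give 0 and the 12 genes were picked for the pattern. The day of induction therefore stays open beside another origin and changed gene models.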

How the results depend on the processing

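The settings of list members at 10 CPM, short introns, the 500 to 1000 UMI profile, the 95th percentile, low-depth day 0 barcodes and 4 or 10 markers, alone or at resolution 1, were chosen after seeing the data, and the rest were set before. No paired analysis was possible because each group is 1 library, no test was run and the replicate number 1 only follows accession order. Of 415 ratios of named genes, 15 changed sign under some setting, 3 of them called as higher: TEK at day 3 against day 0, from 1.12 to a log2 ratio of -0.0791 with TMM, and TAGLN and KRT18 at day 5 against day 3, from 2.66 and 1.09 to -0.0383 and -0.72 with the 500 to 1000 UMI profile subtracted. Those not called include MAP2 at day 3 against day 0, from 0.26 to -0.93 with TMM, and TOP2A at day 5 against day 0, from 0.57 to -0.56 with TMM. Which direction held more genes also changed, and so did the list medians named in the results. More genes were higher than lower at day 3 against day 0 and day 5 against day 0 by CPM, and fewer with TMM, at 1517 against 4861 and 3959 against 5230, while at day 3 against day 0 the median of ratios gave 2101 against 3784. Genes with under 20000 bases of intron gave fewer higher than lower at day 5 against day 3, at 620 against 2541, and against day 0, at 883 against 2155. Of list counts over all settings, 218 moved past their limit and 1465 did not, of values of named genes 1827 and 4622 beside the 3 reversed, of shares 91 and 35, and of other results 28 and 82. Scrublet marked too few cells to leave any out, so keeping doublets equals the reported values, and for list counts no filter on low CPM equals them too. Depth limits the day 3 library most, where 3 UMIs are 0.160 CPM.

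With TMM scaling, day 3 against day 0 gave 1517 genes higher, 4861 genes lower, 5 fibroblast higher, 7 cAMP higher, 27 S phase lower, 29 G2 and M lower, 4 p53 higher, 17 cholesterol lower and 2 nuclear retained higher. There, day 5 against day 0 gave 5230 genes lower, 5 S phase higher, 3 G2 and M higher, 5 cholesterol higher and 10 mitochondrial lower. With median of ratios scaling, day 3 against day 0 gave 2101 genes higher, 3784 genes lower, 6 fibroblast higher, 19 G2 and M lower, 15 cholesterol lower and 2 nuclear retained higher. This gave, in day 5 against day 3, 9 ribosomal lower. Under it day 5 against day 0 gave 6 S phase higher, 7 G2 and M higher and 6 mitochondrial lower. Without mitochondrial and ribosomal genes in the total, day 3 against day 0 gave 11 G2 and M lower. Here day 5 against day 0 gave 5 mitochondrial lower. With the mean of per-cell CPM, day 3 against day 0 gave 11 S phase lower. It gave, for day 5 against day 0, 4 mitochondrial lower. With cells thinned to 1000 UMIs, day 3 against day 0 gave 3 neurotransmitter higher. There, day 5 against day 3 gave 5 ribosomal lower. With no filter on low CPM, day 3 against day 0 gave 9773 genes higher. This gave, in day 5 against day 3, 8625 genes higher and 6319 genes lower. Under it day 5 against day 0 gave 14245 genes higher. With the larger CPM at least 50, day 3 against day 0 gave 1620 genes higher, 1303 genes lower, 0 pan-neuronal higher, 2 neuronal factor higher, 1 progenitor higher, 0 neurotransmitter higher, 5 S phase lower, 3 G2 and M lower, 13 inflammatory higher and 3 cholesterol lower. Here day 5 against day 3 gave 2409 genes higher, 1653 genes lower, 8 neuronal factor higher, 8 progenitor higher, 3 neurotransmitter higher, 6 S phase higher, 9 G2 and M higher, 9 p53 lower and 10 cholesterol higher. It gave, for day 5 against day 0, 2986 genes higher, 1854 genes lower, 9 neuronal factor higher, 7 progenitor higher, 3 neurotransmitter higher, 7 S phase higher, 10 G2 and M higher, 5 p53 lower and 7 inflammatory lower. With list members at 10 CPM, day 3 against day 0 gave 1 pan-neuronal higher, 5 neuronal factor higher, 2 progenitor higher and 0 neurotransmitter higher. There, day 5 against day 3 gave 13 neuronal factor higher and 8 neurotransmitter higher. This gave, in day 5 against day 0, 14 neuronal factor higher and 8 neurotransmitter higher. With under 20000 bases of intron, day 3 against day 0 gave 1453 genes higher, 1149 genes lower, 1 fibroblast higher, 8 contractile lower, 3 pan-neuronal higher, 5 neuronal factor higher, 3 progenitor higher, 4 neurotransmitter higher, 6 cAMP higher, 11 S phase lower, 2 G2 and M lower and 5 cholesterol lower. Under it day 5 against day 3 gave 620 genes higher, 7 fibroblast lower, 4 contractile lower, 8 pan-neuronal higher, 12 neuronal factor higher, 9 progenitor higher, 7 neurotransmitter higher, 7 S phase higher, 2 G2 and M higher and 10 p53 lower. Here day 5 against day 0 gave 883 genes higher, 8 fibroblast lower, 9 contractile lower, 8 pan-neuronal higher, 13 neuronal factor higher, 8 progenitor higher, 7 neurotransmitter higher, 2 S phase higher and 0 G2 and M higher. With every day 5 barcode of 1000 UMIs, day 5 against day 3 gave 4 oxidative phosphorylation lower and 3 ribosomal lower. It gave, for day 5 against day 0, 1 mitochondrial lower. With the strict filter, day 5 against day 3 gave 7 oxidative phosphorylation lower and 3 ribosomal lower. With the 500 to 1000 UMI profile subtracted, day 5 against day 3 gave 13 contractile lower, 30 oxidative phosphorylation lower and 29 ribosomal lower. There, day 5 against day 0 gave 6 mitochondrial lower.

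At least 2 UMIs of the G2 and M phase list were seen in 61.5% of day 0, 68.9% of day 3 and 88.6% of day 5 cells thinned to 2000 UMIs, in 71.3%, 67.5% and 99.05% without thinning, and in 44.5% and 40.4% of day 0 and day 3 cells with the strict filter. Neuron-like clusters held 29.8% of day 5 cells at resolution 0.25, 27.2% with at least 4 markers, 17.6% with at least 10, and 17.1% at resolution 1 with at least 4 or 10. Resolution 1 gave 12 clusters at day 0 and 7 at day 3, and resolution 0.25 gave 5 at day 5. Calling every barcode of 1000 UMIs put the cells kept in the day 5 library at 16614. Apart from settings that by construction compare fewer genes or members, the cause was not tested.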

Other observations

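The lists were set before the data were examined, and the counts at 10 CPM or more were chosen after the result was seen. No hypothesis beyond those weighed above was tested.

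Genes of other neural and embryonic groups differed at day 5. The neural crest and dorsal neural tube factor PAX3 stood at 166 CPM with 1 UMI at day 3 and 0 at day 0, in a Schwann and neural crest list with 6 of 10 members higher and 3 lower than at day 3. The RNA-binding gene LIN28B stood at 182 CPM with 1 UMI at day 3, and of the pluripotency list 4 of 7 members were higher and 2 lower. In the glial list 4 of 11 were higher and 4 lower, with the glutamate transporter SLC1A3 at 274 against 31.7 CPM. The cartilage collagen COL2A1 stood at 184 against 3.63 CPM, in a chondrocyte and osteoblast list with 4 of 9 higher and 1 lower. In the adipocyte list 2 of 8 were higher and 4 lower, with LPL at 310 against 0.214 CPM. Position code genes of dermal fibroblasts had 9 of 11 lower and 1 higher at day 5 than at day 3, with PITX1 at 0.0589 against 166 CPM and TBX5 at 0.314 against 42.7.

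Glycolysis, interferon response, transforming growth factor beta and heat shock genes were mostly lower at day 5 than at day 3, while other metabolic lists, cholesterol synthesis and mitochondrially encoded genes, were mostly higher. Genes outside the neuronal lists with 1000 to 10000 bases of intron had a median log2 ratio of -1.26. The interferon and heat shock medians were -1.65 and -1.46, and those of glycolysis and transforming growth factor beta targets -2.49 and -2.40. Intron length was not matched, so these counts are not set apart from its trend. Glycolysis had 17 of 22 members lower and 1 higher, with LDHA, which makes lactate, at 3.65 against 427 CPM. Interferon response genes had 17 of 24 lower and 3 higher, with B2M at 38.6 against 907 CPM. Transforming growth factor beta targets had 11 of 14 lower and 1 higher, with TGFBI at 0.530 against 1398 CPM, and YAP and TEAD targets had 4 of 15 lower and 3 higher. The unfolded protein and stress response had 11 of 23 lower and 1 higher, with DDIT4 at 5.89 against 233 CPM, and heat shock genes had 8 of 12 lower and 0 higher. Among other lineages, epithelial genes had 5 higher and 3 lower of 12, melanocyte 3 higher and 0 lower of 6, endothelial 3 higher and 4 lower of 8, blood and immune 0 higher and 6 lower of 7, and muscle 0 higher and 3 lower of 7. Of these 5 lists, the members at 10 CPM or more numbered 2, 1, 3, 0 and 0.

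Between day 3 and day 0, heat shock genes had 8 of 12 lower and 0 higher, with HSPB1 at 73.8 against 500.1 CPM. Interferon response genes had 6 higher and 5 lower of 25, with ISG15 at 29.02 against 210 CPM, and glycolysis had 5 higher and 4 lower of 22, with PFKFB4 at 221 against 13.2. Kept day 0 barcodes under 3000 UMIs numbered 6409, 38.2% of kept barcodes and 3.52% of UMIs, and ribosomal protein transcripts took 24.9% of their UMIs against 16.9% in the others.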
